A study of Mus musculus with 8 samples.

How the data were processed

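Gene expression was measured in 8 cultures of C2C12, an established mouse myoblast line that leaves the cell cycle and fuses into multinucleated myotubes when serum is reduced. Of these, 4 cultures carried a lentivirus with siRNA against DOR, the product of Trp53inp2, and 4 carried a lentivirus with scrambled RNA. Per the labels' protocols, cells were transduced at an moi of 100, amplified for 5 to 7 days and sorted for GFP, which gave 93 to 99% GFP-positive cells. They were then kept in medium with 5% horse serum for 4 days, per the same protocols. Other labels call the samples confluent myoblasts and carry a D2 mark of unstated meaning, so the exact stage at harvest is not settled by the labels. Total RNA, 25 ng per sample, was amplified with a whole transcriptome kit and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The labels call the cultures of a group biological replicates without saying how they were derived from the line.

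The deposited values were log2 expression values per probe set made by the authors with RMA, per the submitters' processing notes. RMA corrects background, makes the arrays' distributions alike by quantile normalization and summarises the probes of a probe set. Its version and options are not given in the sources used here, and the scanner files were not used here. Quantile normalization presumes that most genes do not change, so a shift of all transcripts in one direction would not be visible in these values. The array medians lay between 6.14 and 6.20 log2 units. No array equalled another, and correlations between arrays over all probe sets ran from 0.988 to 0.997. The number of arrays limits the precision, and a log2 difference of a dim probe set is compressed toward 0.

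Of the probe sets on the array, 64 were Affymetrix controls and 45037 entered the tests. Probe sets were named through the platform annotation and RefSeq gene identifiers. A single symbol was listed for 34945 probe sets, several symbols for 932 and none for 9160. Identifiers of 34741 of the first kind matched, no symbol was updated, and 18193 genes resulted. Probe sets with several symbols were tested but not named, so some genes of the lists, Gapdh among them, are not analysed here. Each gene was represented by its probe set with the highest mean over the 8 arrays. No genome was used, so no positions are given.

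Groups were compared with limma 3.58.1 in R 4.3.3, fitting the group alone and moderating the variances with eBayes. Two-sided p-values were adjusted by the Benjamini-Hochberg method over all 45037 probe sets, and an adjusted p under 0.05 counted as a call. Differences are DOR siRNA minus scrambled, on the log2 scale, and an error given with a difference is its standard error from the model. Gene lists, 26 in number, were fixed before the data were examined, as were the design, the naming rule and the alternatives except where stated. They were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Camera with an estimated correlation, fry and an exact two-sided permutation test of each list's mean shift per array were run beside it. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. The permutation test was added after the data were seen and does not keep same-numbered arrays paired. With 4 arrays against 4 it cannot go below 0.0286. Figures were drawn with matplotlib 3.10.9.

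Genes were named by a rule. It took Trp53inp2 with all its probe sets and the 12 largest increases and 12 largest decreases among called genes. Those genes also had to show no overlap between the groups and a higher group mean at or above 6.18, the median of all probe sets. In each list it took up to 4 called members with the smallest p, or the 2 members with the smallest p, as values, where none was called. A gene named outside this rule is marked as chosen after its values were seen.

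The steps were tested on simulated data of 45037 probe sets in 4 against 4 arrays, with 200 changed probe sets, over 10 runs. The test recovered 44.8% of changes of 0.5 log2 units, 90% of changes of 1, 96.8% of changes of 1.5 and 98.6% of changes of 2, and 4.90% of its calls were false. A list shifted by 0.3 was found in 10 of 10 runs, with 0 other lists called, although the simulated genes were independent and real ones are not.

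Both groups carry replicate numbers 1 to 4, and same-numbered arrays also share a letter in their descriptions. Deviations of same-numbered arrays from their group means correlated at 0.142 to 0.468 over all probe sets. Between different numbers the correlations ran from -0.394 to 0.265, and 5 of 8 arrays correlated best with their own number. Since each of the 4 pairs was above 0.1, the numbers were taken as pairing the cultures, and values from the fit with the replicate number as a block (the paired fit, which called 2827 probe sets) are given where they change a call or a count by more than 1.5 times. Other alternatives were a random replicate block, renewed quantile normalization, cyclic loess, leaving out dim probe sets, a variance trend with a robust prior, array weights, the 3′ minus 5′ difference of the Actb and Gapdh control probe sets as a covariate, the mean over a gene's probe sets, a threshold of 0.1 and leaving out each array in turn. A covariate from the poly-A spike-in controls was added after the data were seen, as were the counts of called list members under each alternative.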

Results

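The series holds 8 arrays of C2C12 mouse muscle cells, 4 after knockdown of DOR and 4 with scrambled RNA. DOR, encoded by Trp53inp2, is known as a cofactor of nuclear receptors, thyroid hormone receptor among them, and as a protein of autophagosome formation. The series title places it among candidate genes for type 2 diabetes at the meeting point of mitochondria and insulin signalling. The comparison asks which transcripts differ when DOR is reduced in these cells.

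The target transcript was lower in every knockdown array. The brighter of the 2 probe sets of Trp53inp2 read 11.50, 11.55, 11.43 and 10.92 log2 units in the scrambled arrays and 9.46, 9.93, 9.49 and 9.18 in the DOR siRNA arrays. The mean fell from 11.35 ± 0.29 to 9.51 ± 0.31 (SD, n = 4 each), a 3.56-fold decrease (log2 difference -1.83 ± 0.17, limma adjusted p = 0.00087). The dimmer probe set did not show the fall, with means of 8.01 and 8.15 (difference 0.14 ± 0.08, limma adjusted p = 0.52). Whether the dimmer probe set lies in the same transcript is not known from the sources used here, so neither its value nor the mean over both probe sets, which differed by -0.85, gauges the knockdown.

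Contractile genes were lower and cell cycle genes higher in the knockdown by camera at the preset correlation, but neither list passed with an estimated correlation (adjusted p = 0.26 for both). In total 1452 probe sets passed the threshold, 3.22% of those tested, of which 917 were probe sets higher and 535 probe sets lower in the knockdown. Most differences were small: the median size among them was 0.54 log2 units, and 92 exceeded 2-fold (48 higher, 44 lower). By gene, 566 were higher and 263 lower. The 4 values of one group lay wholly beyond those of the other for 9.85% of probe sets, against 2.86% by chance. Pairing the cultures by number gave 2827 probe sets (1562 higher, 1265 lower). Leaving out 1 array moved the total to between 608 (without scrambled 3) and 2310 (without scrambled 4); it was 627 without scrambled 1, 669 without scrambled 2, 821 without DOR siRNA 1 and 615 without DOR siRNA 3.

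Among the 12 largest decreases, 5 genes encode proteins of the sarcomere. Myh4, a fast myosin heavy chain, fell 5.84-fold (log2 difference -2.55 ± 0.40, limma adjusted p = 0.0087), and the perinatal heavy chain Myh8 also fell (-1.89 ± 0.41 log2 units). Lower values were found too for the heavy chain Myh1 (-1.18 ± 0.19), the regulatory light chain Myl2 (-1.45 ± 0.30) and Actn2 (-1.71 ± 0.20), which cross-links actin in the Z-disc. Mef2c, a transcription factor that drives muscle genes, fell by 1.53 ± 0.16, and 5 of its 5 probe sets passed the threshold in that direction. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, fell by 1.81 ± 0.23, and Trp63, a member of the p53 family, fell by 1.91 ± 0.18. The remaining decreases were Trp53inp2 itself, Dhrs7c (-1.46 ± 0.22), Reep1 (-1.18 ± 0.14) and Cops7a (-1.12 ± 0.08). The knockdown mean of Myl2 (6.07) lay under the median of all probe sets (6.18) and that of Myh4 (6.32) little above it. Neither was shown to be above background, so the sizes and ranks of the falls of Myl2 and Myh4 are not firm.

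By its brightest probe set, the largest of the 12 increases named was that of Npr3, the clearance receptor for natriuretic peptides, which rose by 1.99 ± 0.38 log2 units (limma adjusted p = 0.020), with an SD of 0.99 among the knockdown arrays against 0.21 among the scrambled ones. Spon2, an extracellular matrix protein, rose by 1.63 ± 0.17, the water channel Aqp1 by 1.60 ± 0.15 and the chemokine Cxcl12 by 1.30 ± 0.23. Id3, which blocks the DNA binding of myogenic factors, rose by 1.44 ± 0.31. Pid1, known for its effect on insulin signalling, rose by 1.51 ± 0.25, Pfn2, an actin-binding profilin, by 1.28 ± 0.10 and Alox5ap, needed for leukotriene synthesis, by 1.27 ± 0.08. Ctla2a (1.59 ± 0.33), Lpar4 (1.38 ± 0.29), Klk1b27 (1.30 ± 0.22) and Plscr2 (1.23 ± 0.29) completed the set. The scrambled means of Npr3 (4.48), Lpar4 (5.17), Klk1b27 (6.18) and Plscr2 (6.17) lay at or under the median of all probe sets (6.18) and were not shown to be above background, so the sizes and ranks of these 4 increases are not firm. Of the 12 increases 11, all but Aqp1, had their highest value on DOR siRNA 2, and without that array the 12 kept 76.3 to 98.3% of their size on the log2 scale. Of the 24 genes with the largest changes, 17 kept the call whichever array was left out. The other 7, which were Npr3, Ctla2a, Id3, Lpar4, Plscr2, Myh8 and Myl2, lost it without scrambled 1, 2 or 3 or DOR siRNA 1, 2 or 3, with limma adjusted p between 0.051 and 0.14. A variance trend with a robust prior ended the same 7 calls. The poly-A covariate ended those of Ctla2a, Id3, Plscr2 and Myl2, and cyclic loess that of Plscr2. The mean over a gene's probe sets ended that of Npr3 and halved its rise to 0.98. By that mean the rises of Spon2 (0.96), Cxcl12 (0.61) and Pid1 (0.54) were also smaller by over 1.5 times, as were the falls of Trp63 (-1.16) and Reep1 (-0.69).

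**Figure D1:**
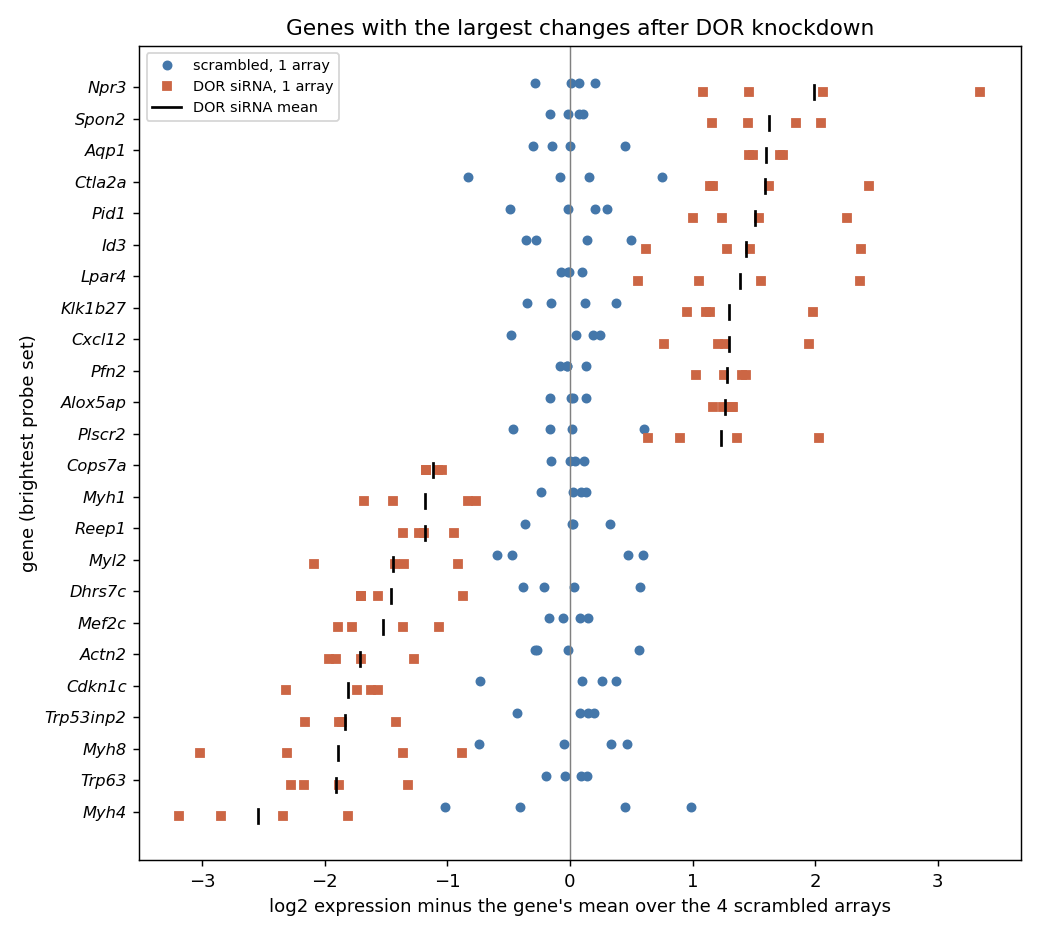
Log2 expression of the 24 genes with the largest changes (vertical axis) relative to each gene's scrambled mean (horizontal axis), with 1 point per array and a black bar for the DOR siRNA mean. The bars run from -2.55 for Myh4 to 1.99 for Npr3, and the groups do not overlap for any of these genes, which was a condition of their choice.

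The sarcomere and contraction list was lower as a whole. Of its 55 measured members, 22 fell and 33 did not pass the limma test; adjusted over the list alone, 48 fell. All 55 differences were negative, with a median of -0.53. These are the brightest probe sets, and another probe set of Tpm1, named after its values were seen, rose past the threshold. Neb, the giant protein of the thin filament, fell by 0.90 ± 0.11, beside Actn2, Myh4 and Myh1 above. The list passed camera (adjusted p = 1.9e-32), with adjusted p = 0.26 with an estimated correlation and an adjusted p of 0.020 by fry. Its mean shift per array was -0.65 ± 0.25 (SD, n = 4) in the knockdown arrays against a spread of 0.23 among the scrambled ones, with no overlap (exact permutation p = 0.029, the smallest possible, and 0.11 adjusted over 26 lists, where at least 15 lists at that p would be needed to pass). Pairing the cultures raised the number that fell to 40, and without DOR siRNA 2 it was 21. It was 30 without scrambled 4, 11 without DOR siRNA 1 or 4, 6 without scrambled 1 or DOR siRNA 3 and 5 without scrambled 2 or 3.

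Cell cycle genes moved the other way. Of 53 members, 24 rose and 29 did not pass the limma test, and adjusted over the list alone 42 rose and 1 fell. The median was 0.45. Ccnd1, the D-type cyclin that couples mitogens to G1, rose by 1.01 ± 0.11, Tk1 of thymidine salvage by 0.81 ± 0.09, Birc5 by 0.68 ± 0.09 and the mitotic kinase Aurkb by 0.66 ± 0.08. Camera at the preset gave an adjusted p of 3.2e-23, with adjusted p = 0.26 with an estimated correlation, and fry 0.0062. The estimated correlation among these genes was 0.21, against the preset 0.01. The 4 knockdown arrays lay above the 4 scrambled ones (mean shift 0.41 ± 0.07, SD; exact permutation p = 0.029, again the smallest possible). The paired fit called 37 members higher, and 23 were higher without DOR siRNA 2, 27 without scrambled 4 and 21 without scrambled 1. The number was 15 without DOR siRNA 4, 14 without scrambled 2, 13 without DOR siRNA 1 and 12 without scrambled 3 or DOR siRNA 3.

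**Figure D2:**
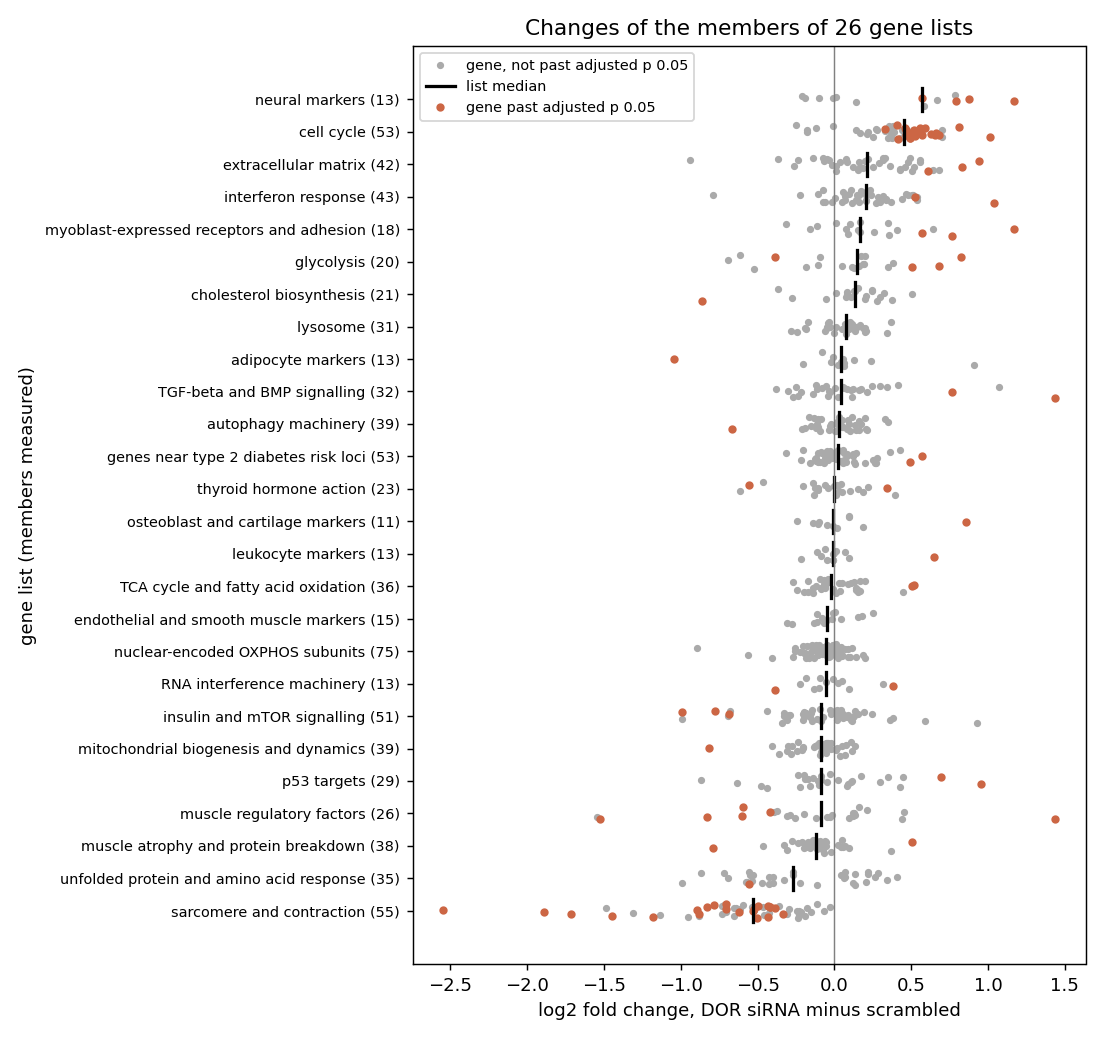
Log2 difference between DOR siRNA and scrambled arrays (horizontal axis) for each measured member of the 26 gene lists (vertical axis), with filled orange points past adjusted p 0.05, grey points not past it and a black bar at each list's median. The sarcomere list has the lowest median at -0.53 and the neural list the highest at 0.57, although without DOR siRNA 2 the neural median was 0.35 and that of the cell cycle list, 0.46, was the highest.

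Regulators of the muscle program changed in part. In the list of muscle regulatory factors 5 of 26 members fell, 1 rose and 20 did not pass; adjusted over the list alone, 9 fell and 3 rose. Mef2c fell as above, Lmod3, which nucleates actin filaments, fell by 0.83 ± 0.12 and the adhesion molecule Ncam1 fell by 0.59 ± 0.11, while Id3 was the member that rose. The other 2 that fell, Smyd1 (-0.60 ± 0.13) and Mef2a (-0.42 ± 0.09), are named after their values were seen. So are some members that did not pass. Of these Myog (-0.31 ± 0.09, limma adjusted p = 0.083), Cav3 (-1.55 ± 0.40, 0.066) and Myod1 (-0.05 ± 0.10, 0.89) were lower. Myf5 (0.45 ± 0.13, limma adjusted p = 0.080) and Pax7 (0.44 ± 0.12, 0.073) were higher, and both passed over the list alone. The means of Pax7 (5.07 and 5.51) lay under the median of all probe sets (6.18) and were not shown to be above background. As a whole the list passed camera downward (adjusted p = 0.0062), with adjusted p = 0.26 with an estimated correlation and 0.037 by fry. Ncam1 lost its call without scrambled 1, scrambled 3 or DOR siRNA 3 (limma adjusted p up to 0.054) and in the mean over probe sets (-0.30, limma adjusted p = 0.078), and Id3 as stated. The paired fit called 2 members higher in place of 1. With scrambled 4 left out 8 fell and 2 rose, 3 fell without scrambled 2 or DOR siRNA 2 or 4, and 2 fell without scrambled 1 or 3 or DOR siRNA 3.

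Receptors and adhesion molecules of myoblasts rose for 3 of 18 members, with 15 not past the limma test (adjusted over the list alone, 7 rose and 1 fell). Cd34, a sialomucin of progenitor cells, rose by 1.17 ± 0.14, Vcam1 by 0.76 ± 0.16 and Pdgfra by 0.57 ± 0.12. Camera called the list upward (adjusted p = 0.0066), with adjusted p = 0.26 with an estimated correlation and 0.020 by fry. Vcam1 and Pdgfra lost their calls without scrambled 1, 2 or 3 or DOR siRNA 1 or 3 (limma adjusted p between 0.060 and 0.11) and with the poly-A covariate (0.053 and 0.067), and Pdgfra also in the mean over probe sets (difference 0.29, limma adjusted p = 0.081). In the paired fit 1 member was lower.

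The mitochondrial lists showed little change in single genes. None of 75 nuclear-encoded OXPHOS subunits passed the limma test, nor over the list alone, against 5 lower and 1 higher at an unadjusted p under 0.05, and the median was -0.055. Without scrambled 2 that median was -0.005, and it was -0.084 without scrambled 1, -0.091 without scrambled 4 and -0.10 without DOR siRNA 1. The members with the smallest p were Cox8b (-0.56 ± 0.20, limma adjusted p = 0.20) and Ndufs8 (-0.41 ± 0.15, limma adjusted p = 0.21). Cox8b passed without scrambled 4 (limma adjusted p = 0.045). The list as a whole passed camera downward (adjusted p = 0.0055), with adjusted p = 0.77 with an estimated correlation, 0.70 by fry and 0.54 by camera without scrambled 2, and the paired fit called 2 members lower, Ndufs8 among them (adjusted p = 0.048). In the list of mitochondrial biogenesis and dynamics 1 of 39 members fell, Mfn2, a mitofusin of the outer membrane (-0.82 ± 0.13, and -0.42 as the mean over its probe sets). That list passed camera downward too (adjusted p = 0.00059), with adjusted p = 0.39 with an estimated correlation and 0.17 by fry, and the paired fit, like that without scrambled 4, called 2 lower. Over the list alone, 1 member of it was lower. Another probe set of Slc25a4, named after its values were seen, passed upward, against the direction of the list. Of 36 genes of the TCA cycle and fatty acid oxidation 2 rose, also over the list alone, Cpt1a, which admits fatty acids to mitochondria (0.52 ± 0.09), and Pdk1, a kinase that restrains pyruvate dehydrogenase (0.51 ± 0.11). That list did not pass camera (adjusted p = 0.96), and its median (-0.022) and mean (0.025) differed in sign. Another probe set of Idh3b, named after its values were seen, passed upward. Pdk1 lost its call without scrambled 1 or 3 or DOR siRNA 1, 2 or 3 (limma adjusted p up to 0.095), with the poly-A covariate (0.063) and in the mean over probe sets (0.13).

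Insulin and mTOR signalling genes fell for 3 of 51 members, with 48 not past the test (over the list alone, 7 fell and 4 rose). These were the growth factor Igf2 (-0.99 ± 0.16), Tbc1d1 (-0.68 ± 0.08), a GTPase-activating protein of glucose transporter traffic, and Prkaa2 (-0.78 ± 0.18), a catalytic subunit of AMPK. The insulin list passed camera downward (adjusted p = 0.012), with adjusted p = 0.60 with an estimated correlation, 0.46 by fry, 0.054 by camera without scrambled 1 and 0.094 without DOR siRNA 4. Another probe set of Slc2a1, named after its values were seen, passed upward, against the direction of the list. The paired fit called 7 lower. Leaving out scrambled 4 gave 7 lower and 1 higher, leaving out DOR siRNA 2 gave 6 lower, and leaving out any other array gave 2 lower. Prkaa2 kept its call only without scrambled 4 among the arrays left out in turn (limma adjusted p up to 0.13), and lost it with the poly-A covariate (0.094). Genes near type 2 diabetes risk loci rose for 2 of 53, Hmga2 (0.57 ± 0.11) and Prc1 (0.50 ± 0.09), a cytokinesis gene that the cell cycle list also holds. Over the list alone 4 rose, and camera gave an adjusted p of 0.76. Other probe sets of Tcf7l2 and Kif11, named after their values were seen, passed upward, while their brightest did not pass. Hmga2 lost its call without scrambled 1, scrambled 3 or DOR siRNA 3, and Prc1 without scrambled 3 (limma adjusted p = 0.055 each at most), and 1 member was lower without scrambled 4.

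Genes of the processes in which DOR is known to act held few called members, and none of their lists passed camera. Over all 18193 genes 829 were called by the brightest probe set, a share at which lists of this size would hold few as well. Fry's mixed test asks whether members change in either direction. It gave adjusted p = 6.1e-06 (autophagy), 3.4e-05 (thyroid hormone action) and 0.0037 (lysosome), but most of the 26 lists passed it. Among 39 autophagy genes 1 fell, Atg4b, a protease that processes LC3-family proteins (-0.67 ± 0.07, limma adjusted p = 0.0011, and -0.37 as the mean over its probe sets), and the list did not pass camera (adjusted p = 0.96). Over the list alone 1 fell and 1 rose, and the paired fit, like that without scrambled 4, called 1 higher beside it. Another probe set of Gabarapl1, named after its values were seen, passed upward, while its brightest did not pass. None of 31 lysosomal genes passed the limma test by the brightest probe set, nor over the list alone, although another probe set of Npc2 passed upward and another of Atp6v1h, named after its values were seen, downward, against 5 higher and 2 lower at an unadjusted p under 0.05. Glb1 (0.37 ± 0.10, limma adjusted p = 0.081) and Npc2 (0.34 ± 0.10, limma adjusted p = 0.093) had the smallest p and passed in the paired fit (adjusted p = 0.042 and 0.034); Npc2 also passed without scrambled 4 (0.028), where 1 member was lower. Camera gave the lysosome list an adjusted p of 0.43. Its mean shift was small, 0.047 in the knockdown arrays, but separated the groups fully (exact permutation p = 0.029, the smallest possible). Among 23 genes of thyroid hormone action Atp2a2, the calcium pump SERCA2, fell by 0.55 ± 0.09 (-0.28 as the mean over its probe sets), and Me1, malic enzyme, rose by 0.34 ± 0.08 (2 lower and 2 higher over the list alone); the list's adjusted p was 0.45 by camera. In the paired fit 3 were lower and 2 higher, without scrambled 4 the lower ones numbered 3 and without DOR siRNA 2 they numbered 2. Me1 lost its call without any 1 of 7 arrays, the exception being scrambled 2 (limma adjusted p up to 0.12), and with the poly-A covariate (0.068).

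**Figure D3:**
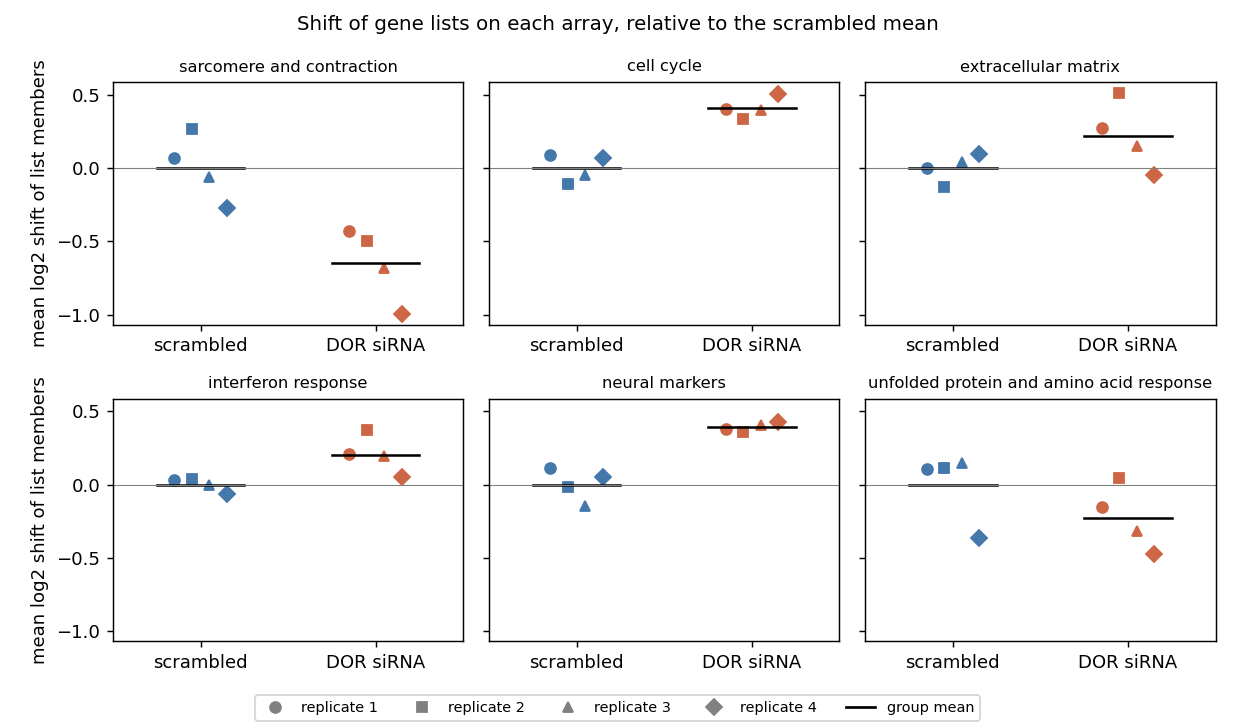
Mean log2 shift of the members of 6 gene lists on each array, relative to the scrambled mean (vertical axis), for scrambled and DOR siRNA arrays (horizontal axis), with marker shape for the replicate number and a black bar for the group mean. The knockdown arrays lie between -0.43 and -0.99 for the sarcomere list and between 0.33 and 0.50 for the cell cycle list, while scrambled 4 lies at -0.37 for the unfolded protein and amino acid response.

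Among the extracellular matrix genes 3 of 42 rose and 39 did not pass the limma test, and over the list alone 14 rose. Col6a1 (0.94 ± 0.16) and Col6a2 (0.83 ± 0.18) encode collagen VI chains and Nid1 (0.61 ± 0.11) a basement membrane protein. The matrix list passed camera upward (adjusted p = 0.00017), with adjusted p = 0.57 with an estimated correlation and 0.17 by fry, and its shift was uneven: 0.51 on DOR siRNA 2 and -0.05 on DOR siRNA 4. The paired fit and the fit without scrambled 4 each called 7 higher, and the paired fit 1 lower; 6 were higher without DOR siRNA 4 and 1 without DOR siRNA 3. Col6a2 lost its call without scrambled 1 or 2 or DOR siRNA 1, 2 or 3, and Nid1 without DOR siRNA 3 (limma adjusted p up to 0.096). The poly-A covariate also ended the call of Col6a2 (0.72 ± 0.18, limma adjusted p = 0.065). Interferon response genes rose for 2 of 43, Ifi27l2a (1.04 ± 0.14) and Ddx58, a sensor of viral RNA (0.53 ± 0.09), and over the list alone 12 rose and 1 fell. This list passed camera as well (adjusted p = 5.3e-05), with adjusted p = 0.32 with an estimated correlation and 0.038 by fry, and its shift was again highest on DOR siRNA 2, at 0.37. Pairing raised the number higher to 9, with 1 lower, 5 were higher without DOR siRNA 4, and 1 was lower without scrambled 4. Ddx58 lost its call in the mean over probe sets (limma adjusted p = 0.058). DOR siRNA 2 also stood apart in its control probe sets, with a 3′ minus 5′ difference of the poly-A spike-ins of 1.76 against at most 1.25 on the other 7 arrays. Without it the medians of the matrix and interferon lists were 0.16 each, against 0.21 each with it, and both lists passed camera. Its absence moved the medians of the neural list (0.57 to 0.35) and the unfolded protein list (-0.27 to -0.42) by over 1.5 times. Both of these passed camera there too, though with all arrays neither did with an estimated correlation (adjusted p = 0.26 and 0.53), nor did the matrix and interferon lists.

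In the unfolded protein and amino acid response 1 of 35 members fell, the serine synthesis enzyme Psat1 (-0.55 ± 0.13), also over the list alone. Camera called that list downward (adjusted p = 0.030), with adjusted p = 0.53 with an estimated correlation and 0.46 by fry. By camera it was not past the threshold without scrambled 1 (adjusted p = 0.060), scrambled 3 (0.11), DOR siRNA 3 (0.098) or DOR siRNA 4 (0.095), and the paired fit and the fit without scrambled 4 each called 10 members lower, with 1 and 4 higher. Psat1 lost its call without any 1 of 6 arrays, the exceptions being scrambled 4 and DOR siRNA 2 (limma adjusted p up to 0.14). Among 38 genes of muscle atrophy and protein breakdown the ubiquitin ligase Trim63 fell by 0.79 ± 0.18 and Cast, the calpain inhibitor, rose by 0.51 ± 0.10, a change opposite to the list's direction; over the list alone 3 fell and 2 rose. This list passed camera downward (adjusted p = 0.00017), with adjusted p = 0.32 with an estimated correlation and 0.059 by fry. The paired fit called 2 higher and 2 lower, and the fit without DOR siRNA 2 called 3 lower. Trim63 lost its call without scrambled 1, 2 or 3 or DOR siRNA 1 or 3, and Cast without scrambled 1, 2 or 3 or DOR siRNA 3 or 4 (limma adjusted p up to 0.12).

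Markers of cell types other than muscle were measured as a check on the cultures. Neural markers rose for 4 of 13 members, Nefl (1.17 ± 0.25), Gap43 (0.87 ± 0.14), Tubb3 (0.79 ± 0.10) and Stmn2 (0.57 ± 0.12), and over the list alone 7 rose and 1 fell. All 4 encode proteins of the neuronal cytoskeleton or growth cone. The neural list passed camera upward (adjusted p = 0.0066), with adjusted p = 0.26 with an estimated correlation and 0.012 by fry. Its median of 0.57 was 0.35 without DOR siRNA 2, 0.33 with the poly-A covariate and 0.32 with the mean over probe sets. Nefl lost its call without scrambled 2 or any 1 of the 4 DOR siRNA arrays, and Stmn2 without scrambled 2 or 3 or DOR siRNA 1, 3 or 4 (limma adjusted p up to 0.094). A variance trend (0.059) and the poly-A covariate (0.051) ended the call of Nefl too. Single members moved in the adipocyte list (Cd36, -1.05 ± 0.17), the osteoblast and cartilage list (Phex, 0.85 ± 0.14, or 0.48 as the mean over its probe sets) and the leukocyte list (Cd14, 0.65 ± 0.10), whose camera adjusted p-values were 0.96, 0.96 and 0.77. Over the list alone, these 3 lists held 1 lower and 1 higher, 1 higher and 1 higher. Both group means of Phex (4.84 and 5.69) lay under the median of all probe sets (6.18) and were not shown to be above background. In the osteoblast list the median (-0.009) and mean (0.055) differed in sign, and in the leukocyte list the median and the camera direction were negative while the mean was 0.020. None of 15 endothelial and smooth muscle markers passed the limma test, nor over the list alone; 2 were lower at an unadjusted p under 0.05, Smtn (-0.27 ± 0.09, limma adjusted p = 0.16) and Vwf (-0.31 ± 0.14, limma adjusted p = 0.31). Camera gave that list an adjusted p of 0.41. In the paired fit 1 adipocyte marker was higher.

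The remaining lists did not pass camera. Among 20 glycolytic genes Pfkl (0.82 ± 0.09, or 0.51 as the mean over its probe sets), Pgam1 (0.68 ± 0.10) and Hk1 (0.50 ± 0.11) rose while Eno3, the muscle enolase, fell by 0.39 ± 0.09 (7 higher and 3 lower over the list alone, camera adjusted p = 0.14, and 0.038 by fry); the paired fit, like that without scrambled 4, called 3 lower. Eno3 lost its call without any 1 array but scrambled 4, and Hk1 without scrambled 1, 2 or 3 or DOR siRNA 3 or 4 (limma adjusted p up to 0.13). With the poly-A covariate Eno3 lost it as well (0.059). In cholesterol biosynthesis Dhcr7 fell by 0.86 ± 0.18, against a positive list median of 0.13 (1 higher and 2 lower over the list alone, camera adjusted p = 0.15, and by camera 0.0078 without scrambled 4, 0.027 without DOR siRNA 2 and 0.0073 with the poly-A covariate). With all arrays the cholesterol list passed neither camera with an estimated correlation (adjusted p = 0.67) nor fry (0.30). The paired fit called 3 members of it higher, and the fit without scrambled 4 called 4. Dhcr7 lost its call without scrambled 1, 2 or 3 or DOR siRNA 3 or 4 (limma adjusted p up to 0.10). Among 29 p53 targets Ddit4l (0.95 ± 0.21) and Dram1 (0.69 ± 0.12) rose, 4 rose and 1 fell over the list alone, and the list's camera adjusted p was 0.66; pairing called 4 lower, and leaving out scrambled 4 gave 2 lower and leaving out DOR siRNA 2 gave 1. Ddit4l lost its call without scrambled 1, 2 or 3 or DOR siRNA 1, 2 or 3 (limma adjusted p up to 0.12), with a variance trend (0.055) and with the poly-A covariate (0.079). In TGF-beta and BMP signalling Id3 and Tgfbr3 (0.77 ± 0.15, or 0.51 as the mean over its probe sets) rose among 32 members (3 over the list alone, camera adjusted p = 0.80), and Tgfbr3 lost its call without scrambled 1, 2 or 3 or DOR siRNA 1 (limma adjusted p up to 0.076). The RNA interference machinery held Ago4 (-0.39 ± 0.08) and Prkra (0.38 ± 0.09) among 13 members (1 lower and 2 higher over the list alone, camera adjusted p = 0.45). Both lost the call when most single arrays were left out, Ago4 except without scrambled 2 or DOR siRNA 4 and Prkra except without scrambled 4 (limma adjusted p up to 0.13). The poly-A covariate ended both (0.052 and 0.086), and a variance trend (0.056) and the mean over probe sets (difference 0.16, limma adjusted p = 0.19) that of Prkra. Both group means of Ago4 (5.69 and 5.31) lay under the median of all probe sets (6.18) and were not shown to be above background.

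In all, 12 of the 26 lists passed camera at the preset correlation, 5 upward and 7 downward, 7 passed fry and none passed with an estimated correlation, where the smallest adjusted p was 0.26. The shift per array separated the groups fully, at the smallest exact permutation p of 0.029, for 7 lists, which were the sarcomere, atrophy, myoblast receptor, cell cycle, interferon, neural and lysosome lists. Their adjusted p was 0.11, and since at least 15 of the 26 lists would have to reach the smallest p for any to pass after adjustment, that value does not count against a single list. The permutation test ignores the pairing of the cultures by number.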

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

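The tests of shorter amplified products and of a wrong label for DOR siRNA 2, and of a condition shared by same-numbered cultures, were chosen after the values were seen. In 110 groups of 4 array values examined for a value far from the other 3, 6 held one (5.45%), which is about the 1 in 20 that chance gives. None of the 64 control probe sets had all 4 DOR siRNA values above all 4 scrambled ones, and 3 had all 4 below, against 0.914 by chance in each direction. Among these 3, the 3′ probe set of the Tfrc control averaged 8.27 in the scrambled and 7.23 in the knockdown arrays, and the middle one of pyruvate carboxylase 7.45 and 7.13. The remaining one was the middle probe set of Tfrc. These control probe sets are named for mouse genes, so a difference in expression and one between the arrays are not told apart here.

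The array DOR siRNA 2 accounted for 3 of the 6. Its 3′ minus 5′ difference in log2 signal was 0.284 for the Actb and Gapdh controls, against at most 0.094 on the other DOR siRNA arrays, and 1.76 for the poly-A spike-ins, against at most 1.18. Its Tfrc control probe sets averaged 5.11, against 6.67 to 6.90. Between the groups their mean was 7.43 in the scrambled and 6.36 in the DOR siRNA arrays (exact permutation p = 0.057). The poly-A difference lay 6.36 SD above the mean of the other 7 arrays (1.11, SD 0.10), as shorter amplified products on that array would give. The same value had flagged the array, so this is no separate test of that explanation. The 18S signal of DOR siRNA 2 was 9.20 against at most 8.13. A scrambled culture under the wrong label is argued against, since its Trp53inp2 value lay below the lowest scrambled array by 5.86 SD of the other DOR siRNA arrays. Shorter products may also bear on its high values in the matrix and interferon lists, which stays open. With the poly-A difference as a covariate the medians of these lists were 0.16 each, as they were without this array, against 0.21 each, and both lists passed camera at the preset correlation in either fit, with 3 members of each higher under the covariate. With all arrays, camera with an estimated correlation called neither the matrix list (adjusted p = 0.57) nor the interferon list (0.32). Without this array 1354 probe sets were called.

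Scrambled 4 stood apart in the unfolded protein and amino acid response, with a mean shift of -0.366 against 0.106 to 0.149 on the other scrambled arrays. Trib3, a pseudokinase induced by amino acid shortage, read 7.69 there against 10.38 to 10.59. A condition shared by cultures of the same number, such as the age of the medium, is a candidate explanation, and 16 of the 35 members were lowest in replicate 4 of both groups. Scrambled 4 was singled out for its low values, being the lowest of its group for 21 members, and DOR siRNA 4 was so for 17, which alone gives 10.2 in both if the arrays are unlinked. Members of a list are not independent either, so by this count a shared condition and coincidence cannot be told apart. Replicate 4 was also lowest of both groups in other lists, such as the sarcomere (-0.27 and -0.99) and insulin lists (-0.14 and -0.24). In the matrix list scrambled 4 was instead the highest of its group (0.09) and DOR siRNA 4 the lowest (-0.05). Over all probe sets the replicate 4 arrays had the highest correlation of any pair, 0.468. What these cultures shared is not known. A biological difference of the knockdown remains open for this list, whose members called lower number 10 in the paired fit.

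Scrambled 2 had the lowest mean shift of the scrambled arrays in the list of myoblast receptors and adhesion, -0.095 against 0.022 to 0.042. It had the highest in the muscle atrophy list, 0.040 against -0.014 to -0.012.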

How the results depend on the processing

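The poly-A covariate and the member counts of lists under each alternative were added after the data were seen. Trp53inp2 kept its call under all alternatives, with differences from -2.02 to -0.85. No called result changed direction under any alternative run. The number of probe sets past the threshold, with those higher and lower, was 2827 (1562, 1265) in the paired fit with the replicate block, 2723 (1632, 1091) with a random replicate block, 2628 (1477, 1151) with array weights, 2634 (1544, 1090) with the Actb and Gapdh covariate and 2682 (1618, 1064) at a threshold of 0.1. Leaving out 1 array gave 608 to 2310 in total, 377 to 1299 higher and 197 to 1011 lower, of which the drop in part follows from fewer arrays; for the other shifts the cause was not tested. Of the 1452 probe sets, 1439 were also called in the paired fit and 591 without scrambled 3. Of 26 lists, 0 passed with an estimated correlation and 7 by fry, and 10 to 13 with 1 array left out. The block changed the call of no list, and of named genes only those of Glb1, Npc2 and Ndufs8. Calls of 29 of 70 named genes ended at least once when 1 array was left out. The variance trend ended those of Npr3, Ctla2a, Id3, Lpar4, Plscr2, Myh8, Myl2, Ddit4l, Prkra and Nefl, and the mean over probe sets those of Npr3, Ncam1, Pdgfra, Pdk1, Ddx58 and Prkra. The poly-A covariate ended 15, those of Ctla2a, Id3, Plscr2, Myl2, Vcam1, Pdgfra, Me1, Pdk1, Prkaa2, Eno3, Ddit4l, Ago4, Prkra, Col6a2 and Nefl, with limma adjusted p from 0.051 to 0.095. Their differences kept a median of 88.3% of their size, 12 of them being smaller, and the standard error was larger for 13. Cyclic loess ended that of Plscr2. The mean over probe sets moved the differences of 16 called genes among those named by over 1.5 times, which no other alternative did for any of them. Among lists that passed camera, the median of the muscle regulatory factors (-0.086) was -0.20 with dim probe sets left out and -0.13 to -0.15 without scrambled 1, scrambled 4 or DOR siRNA 3, and that of the insulin list (-0.084) was -0.03 without scrambled 2 and -0.13 with the poly-A covariate, which also gave -0.47 for the unfolded protein list. Leaving out dim probe sets ended that of the unfolded protein list (adjusted p = 0.063). The cholesterol list passed camera with array weights and with the poly-A covariate, but not with an estimated correlation (adjusted p = 0.67) or by fry (0.30). List medians not past the threshold changed sign 19 times with 1 array left out and 19 times under other settings. Probe sets other than the brightest added further members in the main fit, named after their values were seen. These were Ryr1 and Ttn downward in the sarcomere list and Foxm1, Gins2, Kif11 and Mcm5 upward in the cell cycle list. Eif2ak2 (interferon) and Slc2a1 (glycolysis) were added upward, and Atf6 (unfolded protein) and Traf6 (atrophy) downward. Values near the floor of the array compress differences, and no background signal was used here to mark them. Some sarcomere genes lay near the top, such as Acta1 (scrambled mean 14.70) and Myl1 (14.65), where the highest value on any array was 15.13. Whether differences are compressed there was not tested, so the sizes of the falls of such genes are not firm either.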

Other observations

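The test of one common fall, the poly-A covariate and the separate count of splits that part all pairs were chosen after the values were seen. Imprinted genes were looked at because Cdkn1c (-1.81) and Igf2 (-0.99) were among the decreases; Cdkn1c restrains and Igf2 drives growth, and both are imprinted. The hypothesis that imprinted genes fall as a group was tested on 26 further imprinted genes whose values had not been seen. It did not hold: camera gave p = 0.78, with the direction up (p = 0.86 with an estimated correlation). Ndn (0.92 ± 0.21, limma adjusted p = 0.039) and Sgce (0.53 ± 0.09, limma adjusted p = 0.012) rose, and none of the 26 fell past the limma threshold, although Zim1 and Kcnq1ot1 were lower at an unadjusted p of 0.042 and 0.022. The 5 genes seen beforehand, Cdkn1c, Igf2, Grb10 (-0.68), Igf2r (-0.20) and Dcn (0.56), had a median of -0.68. Since Cdkn1c and Igf2 prompted the question, this median is no test of it.

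The cause of the lower contractile and higher cell cycle genes is not settled. With the poly-A difference as a covariate the medians were -0.58 and 0.47, against -0.54 and 0.46 without DOR siRNA 2. The covariate mostly marks that array (1.76, against 0.92 to 1.25 on the other 7), and the groups otherwise overlap in it. Shorter products on DOR siRNA 2 are thus argued against as the whole cause, while other differences in amplification were not tested. A smaller share of differentiated cells, all else equal, would lower genes exclusive to those cells by one amount. The 20 contractile genes with scrambled means of 8 to 12 log2 units instead differed by -2.55 to -0.36. The SD of their changes (0.56) was 3.12 times their median SE (0.18). Their SEs were uneven, such as 0.51 for Casq1 and 0.08 for Chrnb1. The median SE thus understates the scatter that a common fall would give, and the ratio overstates the difference. The -2.55 is the change of Myh4, whose size is not firm. Some members may be expressed in undifferentiated cells too, the bounds were chosen with the values in view, and delayed differentiation, a loss of late genes in each cell and effects of the siRNA on other transcripts stay open, untested.

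Among the 35 splits of the 8 arrays into 4 and 4, 1 gave as many probe sets past the threshold as the real 1452, which is the real one; the highest other gave 274. The same held for those higher, where 1 split reached 917 and the highest other 218, and for those lower, where 1 reached 535 and the highest other 56. With the replicate numbers set aside, that is a share under 0.05 for these counts, and the smallest that 35 splits can give. Since the numbers were taken as pairing the cultures, this does not exclude chance. With the pairing kept, only the 8 splits that part all 4 same-numbered pairs compare with the real one. The highest other of these gave 0 for each of the 3 counts, and 8 splits are too few for a share under 0.05. For the gene lists chance cannot be excluded over all splits: 4 of the 35 gave as many as the real 12, the highest other 15 and the median other 6, so the preset correlation calls lists on regrouped arrays as well. The 3 others that gave as many part 2 of the 4 pairs each. Among the 8 that part all 4, the highest other gave 11, and these too are too few for a share under 0.05.

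Npr3, Negr1, Col11a1 and Scara3 varied widely among the knockdown arrays, with SDs of 0.99, 1.39, 1.17 and 1.27 against 0.21, 0.23, 0.38 and 0.16 in the scrambled ones. They were chosen after their values were seen, and all but Npr3 missed the limma threshold. All 4 were highest on DOR siRNA 2, the array that stood apart in its control probe sets, and without it the SDs of the knockdown arrays were 0.49, 0.71, 0.58 and 1.00.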
